A study of Oryza sativa with 18 samples.

How the data were processed

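Total RNA had been extracted with Trizol and size-fractionated, per the labels, from WT and 2 knock-down lines, ago18(1) and ago18(2), in seedling, young panicle and mature panicle. The 18 deposited files, 1 per library, list each distinct read sequence of 16 to 36 nt with its count, and the unit is a raw count of reads. This was read from the values, which are whole numbers with each sequence listed once. How the authors removed adapters, chose lengths and filtered reads is not given in the sources used here, nor is any aligner or genome build. Groups and replicate numbers were taken from the sample titles.

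No genome was used here. The plan fixed before the data were examined held a fallback for this case, which was followed: the features were miRNA families and each remaining distinct sequence of 20 to 24 nt. Phased-siRNA loci, genome windows and reads of AGO18 were therefore not analysed here. A family was the sum of exact matches to its listed mature sequences. The list, 55 sequences in 31 families and 6 groups, was written from general knowledge of rice miRNAs before the data were examined, and 22-nt reads with up to 2 mismatches also counted for miR2118 and miR2275. The groups were phase change and inflorescence, development and hormone, nutrient and stress, small RNA machinery, monocot-specific families, and triggers of phased siRNAs. The libraries held 13425353 distinct sequences of 20 to 24 nt, and 259277 with at least 15 reads over all libraries entered the working table. The alternative with a lower minimum count was run on the same table.

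Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Features were kept by filterByExpr at a minimum count of 20 over the 9 groups, which left 27940, and scaled by TMM. One quasi-likelihood fit held all 18 libraries with a coefficient for each group, leaving 9 residual degrees of freedom and a biological coefficient of variation of 11.12%. The effect of ago18 in a tissue was the mean of the 2 lines minus WT. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all features, and over the list alone for the families. Robust, non-legacy quasi-likelihood options were set after a fit with the default options had been seen, and the default counts are among the alternatives. Groups of features were tested with camera at a preset correlation of 0.01 and with an estimated one. They were also tested with fry, as planned, which asks whether a group changed at all rather than more than the other features. Adjusted p values of groups are from camera unless fry is named. Fry is given where it passed and camera did not.

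The features named were set by a rule fixed in advance: up to 12 families by p past the threshold with the same sign in both lines, the 5 single sequences of largest change among those past the threshold with the same sign in both lines and a mean of at least 5 CPM, and miR168, miR528, miR390, miR2118 and miR2275 in every ago18 comparison. For WT tissues the rule took the 5 families that rose and the 5 that fell most, and miR156, miR172, miR2118 and miR2275. Members of the fixed groups outside the rule are named only where they make up a count. Fold changes against 0 reads are lower bounds against a floor of 3 counts over the group, and ratios on 1 to 3 reads carry 95% counting intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

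Read-length shares were tested by exact two-sided permutation of the genotype labels within each tissue and over the tissues together (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Shares of single libraries carry Wilson 95% intervals. Agreement of replicates was checked with a chi-square per degree of freedom, which ran from 1.46 to 6.17 over the 9 pairs, so that no pair agreed within sampling noise alone. Replicate numbers were not used to pair libraries. Deviations from the group mean had a median correlation of -0.0155 over 36 pairs of groups, from -0.366 to 0.484, with 10 pairs over 0.1. The highest was that of WT seedling with WT young panicle.

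The method was tested on simulated data with the fitted spread and 200 changed features of 27940. In seedling, young panicle and mature panicle it recovered 40.0%, 54.0% and 48.7% of 2-fold increases and 94.0%, 96.7% and 98.7% of 4-fold increases. Of 2-fold decreases it recovered 18.7%, 23.3% and 40.0%, and of 1.5-fold increases 11.3%, 12.0% and 8.0%. Among its calls 13.7%, 10.0% and 9.01% were false, above the nominal 5%. Of the unchanged features 0.0469%, 0.0373% and 0.0348% were called. With the default quasi-likelihood options 24.3%, 16.0% and 9.75% of the calls were false on the same draws.

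Alternatives planned before the data were examined were DESeq2 size factors, the total as the only scaling, DESeq2 1.42.0, a minimum count of 5, only the tissues compared, a replicate block, both lines as 1 group, leaving out each library, 3′ variants within 2 nt, and other bases for the shares. A read-length term, removal of sequences ending in the adapter start, and default quasi-likelihood options were added after the data were seen, and so were the alternatives for single lines and differences between tissues. Figures were drawn with matplotlib 3.10.9.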

Results

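Small RNAs of Oryza sativa were sequenced in 18 libraries of the indica cultivar Pusa Basmati 1. AGO18 is an Argonaute protein found in grasses, and the title of the series links it to male sterility. The libraries came from wild type (WT) and from 2 knock-down lines, ago18(1) and ago18(2). Each was sampled as 4-week-old seedling, young panicle and mature panicle, with 2 libraries for each of the 9 groups. The RefSeq gene table places the AGO18 gene (LOC4343201) on chromosome 7. Its messenger RNA is not measured by these reads, and no position in the genome was assigned to any small RNA here.

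The libraries held between 4118314 and 8182833 reads, of which 1677056 to 4247809 were 20 to 24 nt long. In WT, replicates 1 and 2 had totals of 5487323 and 4644355 reads in seedling, 6798283 and 5891585 in young panicle, and 7737847 and 8182833 in mature panicle. The ago18(1) totals were 7990810 and 5805704 in seedling, 7355511 and 6239673 in young panicle, and 7591909 and 7531885 in mature panicle. Those of ago18(2) were 7744242 and 7940037 in seedling, 4118314 and 7465622 in young panicle, and 7137213 and 7507646 in mature panicle. Tested features were 25 miRNA families, each the sum of its listed mature sequences, and 27915 other single sequences of 20 to 24 nt. The families miR395, miR397, miR399, miR444, miR529 and miR820 were too rare to test, with 0, 74, 34, 3, 69 and 128 reads over all libraries. Levels below are in CPM, read counts scaled to the reads on tested features with TMM factors, as mean ± SD, with n = 2 for WT and n = 4 for the ago18 lines together. A fold change for both lines is the geometric mean of their changes. A lower bound against 0 WT reads, or a ratio on 1 to 3 WT reads, instead uses the mean level of the ago18 libraries. The labels do not say whether replicates came from separate plants, so every adjusted p measures only the spread between these libraries, which may be technical.

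A 21-nt sequence, TAACACTGTGACAATACACCG, set the 12 ago18 libraries apart from the 6 WT libraries. The ago18 libraries held 906 to 6831 reads of it each, or 446 to 1829 RPM, here reads relative to all 20- to 24-nt reads of the library. The WT libraries held 0 reads in 5 cases and 3 reads in the remaining mature panicle library, which was 0.706 RPM. A count of 0 allowed up to 0.749 to 1.38 RPM in these 5 libraries. A partner sequence, TCTCGGTGAATTCTCACAGTG, pairs with it at 16 of 18 overlapping positions, with 3-nt offset ends. That partner had 501 reads over the ago18 libraries and 0 in WT. By this sequence all 18 libraries fell on the side of WT or ago18 that their label gives, but it does not tell one line from the other. The sequence was singled out after its values had been seen, so this is not an independent check of the labels. Whether it comes from the knock-down construct or from rice was not tested, so its rise is not read as a response of rice small RNAs.

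**Figure D1:**
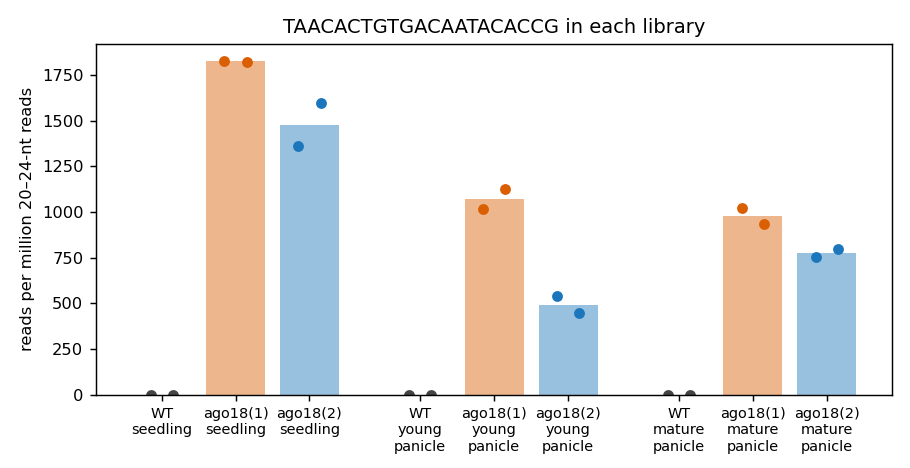
RPM of TAACACTGTGACAATACACCG among 20- to 24-nt reads in each group, with bars for the mean of 2 libraries and points for the libraries, on a linear axis. The ago18 libraries lie between 446 and 1829 RPM and the WT libraries at or below 0.706.

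The first question was whether the size classes of small RNAs shifted with the knock-down, since 21- and 22-nt reads include most miRNAs and 24-nt reads are the class of heterochromatic siRNAs. Shares are percentages of the 18- to 30-nt reads. The 22-nt share was 9.51% ± 0.408 (SD, n = 2) in WT seedlings and 7.0% ± 0.295 (SD, n = 4) in ago18 seedlings, lower in 4 of 4 ago18 libraries. In young panicle it was 7.26% ± 0.0296 in WT and 7.85% ± 0.790 in ago18, and in mature panicle 7.95% ± 0.0362 and 7.87% ± 0.293. The 21-nt share was 13.4% ± 1.00 in WT seedlings and 11.6% ± 0.969 in ago18. It was 9.21% ± 0.0846 and 11.7% ± 1.40 in young panicle, higher in 4 of 4 ago18 libraries, and 11.3% ± 0.117 and 11.6% ± 0.776 in mature panicle. The 24-nt share was 26.4% ± 0.107 in WT seedlings and 26.4% ± 4.22 in ago18, 31.4% ± 0.464 and 23.04% ± 8.97 in young panicle, and 27.8% ± 0.180 and 24.5% ± 6.06 in mature panicle. The 24-nt share differed between the lines. ago18(1) held 30.004%, 30.8% and 29.7% in seedling, young panicle and mature panicle, and ago18(2) held 22.7%, 15.3% and 19.2%. ago18(2) also held more 18- to 30-nt reads outside 20 to 24 nt, with 44.2%, 47.7% and 45.1% against 34.2% to 37.6% in the other groups. In its young panicle libraries a mean of 27.8% ± 13.0 (SD, n = 2) of all reads were of 16 to 19 nt, with the higher share in replicate 1, as given below. A difference in RNA quality is thus not separated from the line. Two-sided exact permutation tests with 15 arrangements per tissue cannot give a p below 0.0667. That value was reached for the 22-nt share in seedlings, and the others ranged from 0.133 to 1. Over the 3 tissues together the exact stratified permutation p was 0.631, 0.113 and 0.191 for the 21-, 22- and 24-nt shares, with mean differences of 0.314, -0.668 and -3.90 percentage points, so no shift common to the tissues was found. The 22-nt result depended on the libraries and base used, as given below. Its difference was -0.783 points without ago18(2) young panicle replicate 1, and changed sign with distinct sequences.

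**Figure D2:**
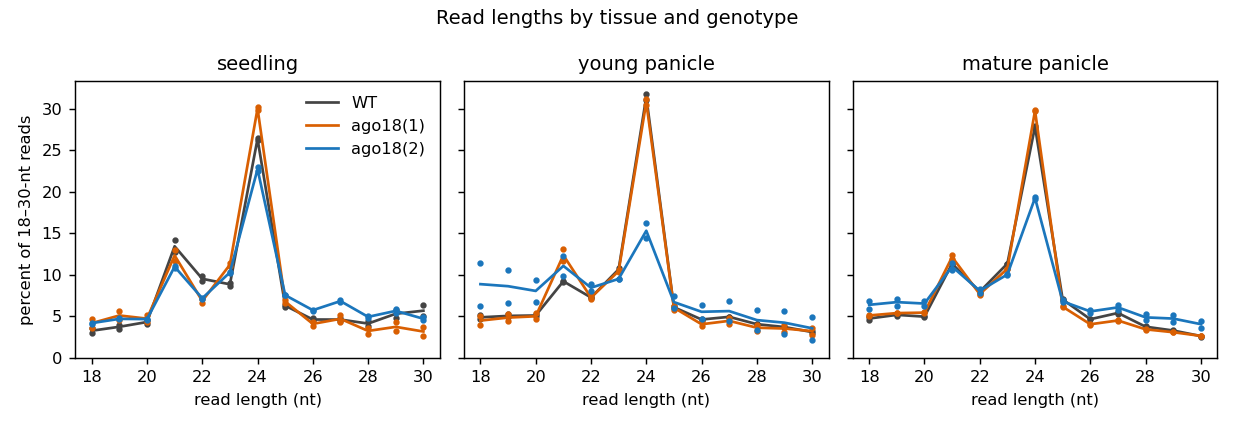
Percent of the 18- to 30-nt reads at each read length (nt) in the 3 tissues, with a line for the mean of 2 libraries of WT, ago18(1) and ago18(2) and points for the libraries. The 24-nt share of ago18(2) lies at 22.7%, 15.3% and 19.2% and that of ago18(1) at 30.004%, 30.8% and 29.7%.

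In seedlings, the vegetative stage, miR398, miR528, miR408 and miR827, which are tied to copper or phosphate supply, were far lower in both ago18 lines. The WT seedling libraries also stood apart from all ago18 seedling libraries in their read ends and longest read, given below, so genotype is not separated here from how these libraries were made. miR398, which targets copper/zinc superoxide dismutases, fell 46.5-fold, from 5506 ± 61.2 to 120.5 ± 28.2 (adjusted p = 9.1e-42). miR528 and miR408, which target copper proteins, fell 30.1-fold, from 432 ± 5.53 to 14.9 ± 5.07, and 12.4-fold, from 1404 ± 143 to 122.7 ± 55.7. miR827, which targets SPX-domain phosphate transporters, fell 8.76-fold, from 877 ± 45.2 to 101.2 ± 24.99. miR169, a regulator of NF-YA transcription factors, fell 5.34-fold, from 64.6 ± 6.57 to 12.7 ± 4.58.

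The related regulators of SPL transcription factors fell too: miR156, which holds plants in the juvenile phase, 4.94-fold from 4646 ± 501 to 948 ± 142, and miR535 5.27-fold from 890 ± 212 to 169 ± 15.9. miR162, which targets Dicer-like 1, fell 3.66-fold from 1003 ± 75.7 to 274 ± 18.2, and miR1432 fell 4.47-fold from 626 ± 26.9 to 159 ± 91.7. miR166, the regulator of HD-ZIP III genes, fell 1.65-fold, and miR390, which triggers trans-acting siRNAs, fell 1.69-fold (adjusted p = 0.00047). miR168, which targets AGO1, was at 15343 ± 1412 in WT and 14702 ± 2493 in ago18 and did not pass (adjusted p = 0.66), though it passed as a decrease with DESeq2 size factors. Higher in both lines were miR159, which targets GAMYB genes, 2.79-fold from 2210 ± 46.1 to 6214 ± 916, and miR2118, which triggers 21-nt phased siRNAs in young anthers, 3.88-fold from 9.40 ± 3.66 to 41.0 ± 21.8. miR2275, which triggers 24-nt phased siRNAs in anthers, had 3 reads in WT seedlings and did not pass (adjusted p = 0.76). Its ratio of ago18 to WT was 9.93, with a 95% counting interval of 3.40 to 48.2, and its level was 34.4 ± 1.84 in ago18(1) and 0.291 ± 0.412 in ago18(2) (n = 2 each).

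Of the 25 families, 2 rose and 18 fell in seedlings, the same counts when adjusted over the list alone. All 5 nutrient and stress families fell. As a group they ranked lower than the other features (camera adjusted p = 7.7e-10, and adjusted p = 0.0047 with an estimated correlation). All 3 phase change and inflorescence families fell (miR156, miR172 and miR535; camera adjusted p = 0.0023, and adjusted p = 0.11 with an estimated correlation). Of the 10 development and hormone families 1 rose and 6 fell (0.0082, and adjusted p = 0.25 with an estimated correlation). Both monocot-specific families, miR1425 and miR1432, fell on the mean of the lines (0.012, and adjusted p = 0.10 with an estimated correlation), though miR1425 rose in ago18(1) and fell in ago18(2) (adjusted p = 0.0038 and 1.4e-11). Of the small RNA machinery families miR162 fell and miR168 did not pass (0.046, and adjusted p = 0.11 with an estimated correlation). Among the phased-siRNA triggers miR2118 rose and miR390 fell (0.77). The 25 families together gave 3.8e-10, and adjusted p = 0.086 with an estimated correlation.

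The 5 single sequences with the largest change in seedlings were GGTAGTTCGACCGTGGAATT and 4 forms of the ago18-marking sequence. Of these, TAACACTGTGACAATACACCG reached 4218 ± 1673 against 0 WT reads, at least 2412-fold higher, and TAACACTGTGACAATACACC, TAACACTGTGACAATACACT and TAACACTGTGACAATACACCT were at least 1579-, 811- and 401-fold higher. GGTAGTTCGACCGTGGAATT, the largest change by fitted size, was at 9906 ± 312 in WT and 0 reads in ago18. It ends in the first bases of a common small RNA 3′ adapter, and reads with such ends occurred only in the 4 WT seedling and WT young panicle libraries. Over all features 5102 rose and 3883 fell in seedlings. By length 913 and 853 of the 21-nt, 690 and 581 of the 22-nt, and 2027 and 1546 of the 24-nt sequences rose and fell, and no size class passed its test (camera adjusted p = 0.77 for each). With DESeq2 size factors the balance turned in all 3 classes, to 757 and 967, 573 and 691, and 1679 and 1840. Their median log2 changes of 0.22, 0.09 and 0.54 lay above 0 while the test pointed lower. At 24 nt the lines went opposite ways under TMM scaling. In ago18(1) 5099 rose and 1154 fell, and in ago18(2) 1188 rose and 1865 fell. The ago18(1) seedlings also held sequences of WT mature panicle, as given below.

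The median log2 change of all features in seedlings was 0.32, and 0.15 with DESeq2 size factors or 0.40 with the total alone, so these counts are relative to the scaling. When differences between the lines entered the spread, 3927 features and 10 families passed, and the calls of miR166 and miR2118 ended. With a term for the longest read length, which parts 35-nt from 36-nt libraries, 3317 features passed and GGTAGTTCGACCGTGGAATT did not, and without WT replicate 2 the call of miR390 ended.

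**Figure D3:**
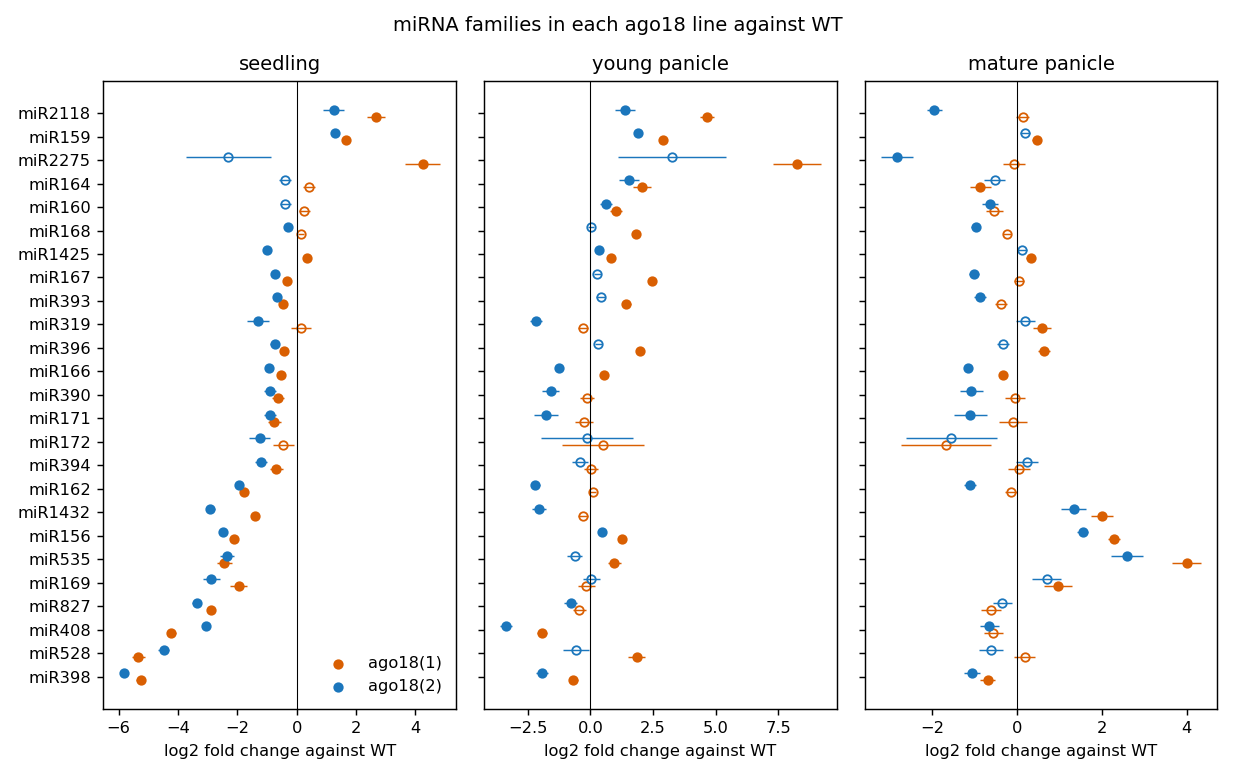
Log2 fold change against WT (x axis) of 25 miRNA families (y axis) in each ago18 line and tissue, with the standard error as bars and filled points for adjusted p under 0.05. miR398 and miR528 lie at -5.26 and -5.34 for ago18(1) in seedlings and at -0.68 and 0.18 in mature panicle.

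In young panicle fewer miRNAs were lower and several were higher, most of all in ago18(1). Across the single sequences, which are not independent replicates, the young panicles of ago18(1) and ago18(2) had r = 0.892 and 0.803 with WT mature panicle and 0.433 and 0.489 with WT young panicle. A difference in panicle stage is therefore not separated from genotype in this comparison. Nor is library making, since both WT young panicle libraries held the adapter-start read ends given below and no ago18 library did. miR159 rose 5.30-fold, from 537 ± 19.6 to 3027 ± 1264 (adjusted p = 1.7e-21). miR2118 rose 8.12-fold, from 5.17 ± 1.98 to 73.4 ± 69.3, with 133 ± 11.3 in ago18(1) and 13.6 ± 0.512 in ago18(2). miR2275 had 0 reads in WT and was at least 10.6-fold higher on the mean level of the ago18 libraries (adjusted p = 0.0040). It stood at 23.03 ± 8.67 in ago18(1), at least 20.7-fold higher, and at 0.537 in ago18(2), under the limit of 1.11 that 0 WT reads allowed. miR408 remained lower, 6.26-fold from 76.4 ± 6.63 to 13.8 ± 7.31, and miR398 fell 2.47-fold from 52.2 ± 10.9 to 23.1 ± 11.8.

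miR156 rose 1.82-fold, miR1425, which targets pentatricopeptide repeat genes, 1.49-fold, miR393, which targets auxin receptors, 1.90-fold, and miR396, which targets growth-regulating factors, 2.20-fold. miR168 rose 1.89-fold on the mean of the lines, with 8488 ± 789 in ago18(1), 2471 ± 537 in ago18(2) and 2425 ± 127 in WT, and the change in ago18(2) did not pass (adjusted p = 0.86). miR167, which targets auxin response factors, rose 2.57-fold on its exact sequences, and this turned to a log2 change of -0.29 when 3′ variants were added. Lower were miR319, which targets TCP genes, 2.35-fold, miR1432, 2.24-fold, and miR390, 1.82-fold. These 3 decreases lay in ago18(2), with 15.7 ± 3.99, 9.77 ± 2.42 and 8.88 ± 1.17 against 68.7 ± 3.16, 39.1 ± 7.72 and 26.3 ± 4.12 in WT, and did not pass in ago18(1) (adjusted p = 0.18, 0.23 and 0.67). The rises of miR167, miR393 and miR396 did not pass in ago18(2) (0.10, 0.052 and 0.071). miR528 was at 5.53 ± 3.55 and 11.9 ± 9.64 and did not pass (adjusted p = 0.18).

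Of the 25 families, 11 rose and 9 fell in young panicle, the same when adjusted over the list alone. By line 14 rose and 2 fell in ago18(1), and 6 rose and 9 fell in ago18(2). Among development and hormone families 6 rose and 3 fell (camera adjusted p = 0.092, and adjusted p = 0.55 with an estimated correlation). In the nutrient and stress list 3 fell, miR398, miR408 and miR827 (0.37), and of the phase change and inflorescence list miR156 rose (0.36). Of the phased-siRNA triggers miR2118 and miR2275 rose and miR390 fell (0.36). Of the machinery families miR168 rose and miR162 fell (0.80), as miR1425 rose and miR1432 fell among the monocot-specific families (0.80). The fall of miR162 lay in ago18(2) and did not pass in ago18(1) (adjusted p = 0.59). In both lists the median was below 0, at -0.07 and -0.29, and the test pointed higher. The 25 families together gave 0.19. By fry the development and hormone list passed as higher (adjusted p = 0.00064), as did the triggers (0.0026) and the 25 families together (0.048). The nutrient and stress list passed fry as lower (adjusted p = 0.00015), and the other lists did not pass.

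The largest decreases were in sequences found almost only in WT young panicle. The 24-nt AAGGCCGAGAGCTGATGACGATCC was at 2554 ± 6.49 in WT and 0.134 ± 0.269 in ago18, and AGATACTGTTTGAAGCATTGCGCC at 544 ± 28.3 and 0. The 21-nt ATGCAAGTGATGTAGCGCCCC was at 4032 ± 201 and 0.823 ± 0.699, and ATGAAGATGAATTGGAACATG at 805 ± 59.6 and 0. TAACACTGTGACAATACACCG was at least 1270-fold higher on the mean level of the ago18 libraries. The origin of these sequences was not determined. Among 24-nt sequences 2308 rose and 4867 fell (camera adjusted p = 0.012, and adjusted p = 0.062 with an estimated correlation), or 1581 and 1361 with the read-length term, against 1371 and 1162 of the 21-nt and 900 and 976 of the 22-nt sequences. The lines parted in the 24-nt class, with 4816 up and 4205 down in ago18(1) and 1437 up and 5795 down in ago18(2). In ago18(2) young panicle 47.7% of the 18- to 30-nt reads lay outside 20 to 24 nt, so RNA quality is not separated from this shift. The 22-nt sequences passed fry as lower (adjusted p = 0.00039) and did not pass camera. Over all features 6362 rose and 8973 fell. Of those that fell, 2604 belonged to the 3204 sequences present at 5 RPM or more in WT young panicle and under 0.3 RPM in every other group, and 6369 did not. Only 2607 of the 3204 were tested, and their fall follows from how the class was chosen. At 24 nt that class made up 2201 of the 4867.

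The median log2 change of all features in young panicle was -0.11, with -0.13 and -0.08 under the other scalings. When differences between the lines entered the spread, 9342 features and 10 families passed and the calls of miR168, miR319, miR1425 and miR1432 ended, and with the read-length term 7701 features passed but not AAGGCCGAGAGCTGATGACGATCC, ATGAAGATGAATTGGAACATG or AGATACTGTTTGAAGCATTGCGCC. Without WT replicate 1 the call of miR390 ended and miR528 passed, and without ago18(2) replicate 2 the call of miR2275 ended.

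In mature panicle the SPL-targeting miRNAs were higher in both lines, the opposite of the seedling. miR535 rose 9.84-fold, from 10.2 ± 1.71 to 112.8 ± 64.2 (adjusted p = 1.7e-05), and miR156 rose 3.78-fold, from 144 ± 15.4 to 561 ± 166. miR1432 rose 3.19-fold, from 7.20 ± 2.57 to 23.6 ± 7.02. All of these fell in WT from young to mature panicle, as given below. A difference in panicle stage is therefore not separated from genotype here either. Across single sequences, which are not independent replicates, the mature panicles of ago18(1) and ago18(2) had r = 0.932 and 0.901 with WT mature panicle. The triggers of phased siRNAs were lower on the mean of the lines, miR2275 2.71-fold from 25.3 ± 2.27 to 13.9 ± 12.1 and miR2118 1.87-fold from 120.6 ± 13.5 to 82.0 ± 59.5. Both decreases lay in ago18(2), with 3.52 ± 0.3997 and 31.1 ± 11.2. ago18(1) stood at 24.4 ± 2.4 and 133 ± 10.4, and neither change passed there (adjusted p = 0.998 and 0.63).

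Smaller decreases were found for miR398 (1.83-fold), miR166 (1.66-fold), miR164 (1.62-fold), miR393 (1.54-fold), miR162 (1.53-fold), miR168 (1.51-fold), miR160 (1.49-fold) and miR390 (1.47-fold, adjusted p = 0.049), and a 1.26-fold rise for miR159 (adjusted p = 0.012). The changes of miR168, miR162, miR160, miR390 and miR393 did not pass in ago18(1), nor those of miR164 and miR159 in ago18(2). The calls of miR390, miR159, miR160 and miR164 ended under several alternatives or without single libraries, that of miR390 also with the total as the only scaling. miR528 was at 15.4 ± 2.33 and 13.8 ± 4.89 and did not pass (adjusted p = 0.58). Of the 25 families 5 rose and 12 fell, and 19 passed when adjusted over the list alone. By line 8 rose and 3 fell in ago18(1), and 3 rose and 12 fell in ago18(2). With the total as the only scaling the split was 7 and 10.

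In the phase change and inflorescence list 2 families rose in mature panicle, miR156 and miR535 (camera adjusted p = 0.029, and adjusted p = 0.20 with an estimated correlation). The phased-siRNA triggers all fell, as did both machinery families (0.029 each, and adjusted p = 0.089 with an estimated correlation). Of the 10 development and hormone families 1 rose and 5 fell (0.046, and adjusted p = 0.35 with an estimated correlation). In the nutrient and stress list miR169 rose and 2 fell, or 4 changed when adjusted over the list alone (0.18). Among the monocot-specific families miR1432 rose, and both passed when adjusted over the list alone (0.046, and adjusted p = 0.13 with an estimated correlation). The 25 families together gave 0.059. By fry the nutrient and stress list passed as lower (adjusted p = 0.018). The 24-nt sequences ranked lower (986 rose and 2199 fell; camera adjusted p = 0.0014, and adjusted p = 0.089 with an estimated correlation). The 22-nt sequences ranked higher (421 rose and 288 fell; 0.046, and adjusted p = 0.038 with an estimated correlation), and 547 and 497 of the 21-nt sequences rose and fell (0.21). Both class shifts were those of ago18(2), with 968 up and 3516 down at 24 nt and 809 up and 231 down at 22 nt. ago18(1) went the other way, with 1454 up and 765 down and with 176 up and 330 down. The ago18(2) mature panicle libraries were among those with more reads outside 20 to 24 nt, and 19.4% of their reads were of 16 to 19 nt, so RNA quality is not separated from these shifts either. DESeq2 gave 217 up and 213 down at 22 nt.

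Again 4 forms of the marking sequence led the changes in mature panicle. TAACACTGTGACAATACACC, TAACACTGTGACAATACACCT and TAACACTGTGACAATACACTT were at least 589-, 176- and 127-fold higher, and TAACACTGTGACAATACACCG, with 3 WT reads, had a ratio of 2146 with a 95% counting interval of 734 to 10408. The 24-nt ATGCACCCGGATACTGTAGAACAC was at 77.2 ± 4.99 in WT and 0 in ago18. Over all features 2837 rose and 3524 fell, which became 3826 and 2659 with the total as the only scaling. When differences between the lines entered the spread, 222 features passed, with miR156 and miR535 as the 2 families among them. Without WT replicate 1 or replicate 2 the count was 3738 or 3491, and with DESeq2 it was 3671.

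**Figure D4:**
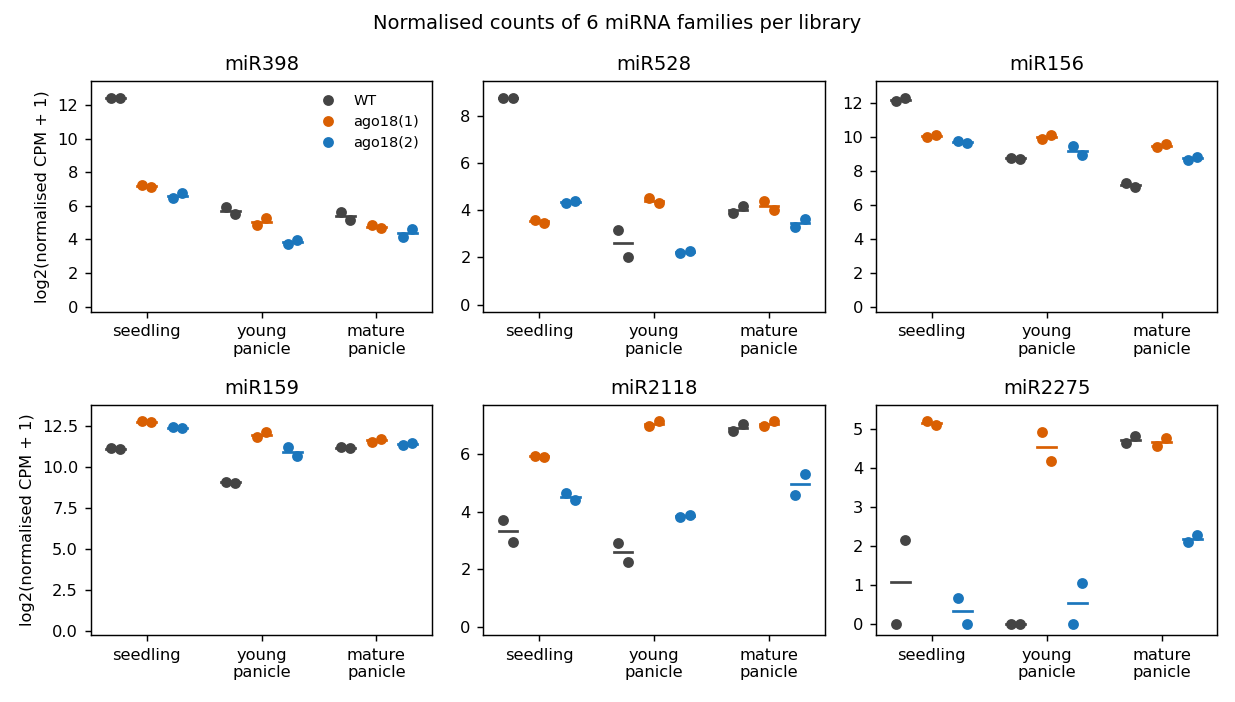
Log2 of normalised CPM plus 1 for 6 miRNA families, with points for the libraries and a line for the mean of the log values of 2 libraries. miR398 falls from 5506 in WT to 120.5 in ago18 seedlings, and miR156 is lower in ago18 seedlings and higher in ago18 panicles.

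The change in ago18 was then compared between tissues, as the difference of log2 changes in one fit. Each difference involves WT seedling or WT young panicle, whose adapter-start read ends no ago18 library held. Library making is therefore not separated from genotype in any of them. Panicle stage is not separated either, since each includes a panicle. Between young panicle and seedling miR528, miR398 and miR156 differed by 5.54, 4.23 and 3.17. Between mature panicle and seedling miR535 differed by 5.69, and miR528, miR398 and miR156 by 4.70, 4.67 and 4.22. miR2118 differed by -3.92 between mature and young panicle. The difference of miR2275 was of the same sign and passed, but it rests on 0 WT young panicle reads and its size is not measured. Differences of miR390 did not pass in any pair of tissues (adjusted p = 1.0, 0.83 and 0.57). Over all features 7368 differed between young panicle and seedling, 6809 between mature panicle and seedling, and 9092 between mature and young panicle. With the lines as 1 group these counts were 3110, 1465 and 2038.

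Each line was also compared with WT. In seedlings 9102 features rose and 3210 fell in ago18(1), and 3655 and 4078 in ago18(2), which became 5324 and 3044 with the total alone. Of these 3196 rose and 2656 fell in both lines, where 1191 and 469 would be shared by independent calls, and 57 went opposite ways. In young panicle 8304 rose and 9671 fell in ago18(1), and 6587 and 8750 in ago18(2) (5029 and 10829 with DESeq2 size factors), with 3182 and 5867 shared against 1958 and 3029. In mature panicle the counts were 2424 and 2056 in ago18(1) (2964 and 1391 with DESeq2 size factors, 3214 and 1241 with the total), and 4420 and 4824 in ago18(2) (2939 and 6231 with DESeq2 size factors). Leaving out 1 library took these totals of 4480 and 9244 to between 2508 and 2920 and between 5920 and 6846. There 855 and 1071 were shared against 383 and 355. Both lines were set against the same 2 WT libraries per tissue, which by itself makes their changes resemble each other. In 20 simulations of lines with no true change and shared controls, at most a mean of 0.20 features per simulation passed with 1 sign in both lines. These drew every library of a tissue from the WT mean with the fitted spread between libraries. They held no variation between lines and no difference in how WT and ago18 libraries were made. The shared calls are therefore not set against these causes, and do not by themselves show a common effect of genotype. The covariance of the log2 changes was 0.24, 0.27 and 0.14 there, against 3.33, 9.40 and 0.763 in the data. The correlation was 0.621, 0.557 and 0.494 there, against 0.630, 0.860 and 0.557 in the data, so in seedling and mature panicle it lay little above that of lines with no true change.

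Set against each other, the lines differed for 8807 features in seedlings, 8296 of them higher in ago18(1) and 511 lower, or 5177 and 2237 with the total alone. In young panicle 17841 differed (9031 higher and 8810 lower, or 11015 and 3792 with DESeq2 size factors), and in mature panicle 9967 (5560 and 4407, or 7677 and 1634 with DESeq2 size factors), the last between 5797 and 7005 with 1 library left out. miR2275 and miR2118 were named above for their difference between the lines.

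WT tissues were compared with the neighbouring stage. WT mature panicle lacked the adapter-start read ends of WT seedling and WT young panicle. Reads ending in 7 adapter bases were also 30.05 times as frequent in WT seedling as in WT young panicle. Library making is therefore not separated from stage in either comparison. From seedling to young panicle 23 of 25 families fell and 1 rose. miR398 fell 105-fold, from 5506 ± 61.2 to 52.2 ± 10.9, miR528 76.6-fold, miR827 34.2-fold and miR156 11.01-fold. The fall of miR528 rests on 11 and 4 young panicle reads and ranged from -6.84 to -5.44 on the log2 scale without single libraries. miR172, which targets AP2-like genes, had 55 reads in seedling and 1 in young panicle, a ratio of 85.6 with a 95% counting interval of 15.4 to 3383. miR319 rose 3.36-fold, from 20.4 ± 0.0339 to 68.7 ± 3.16. miR2118 did not pass (adjusted p = 0.12), and miR2275 had 3 and 0 reads, too few for a fold change. Its call ended without seedling replicate 2 and without either young panicle library. Over all features 13635 rose and 7497 fell, with a median log2 change of 0.83, and of 0.81 or 1.23 under the other scalings. Of those that rose, 2601 belonged to the class found almost only in WT young panicle, a rise that follows from how the class was chosen. Of the 24-nt sequences 7828 rose and 3796 fell. The phased-siRNA triggers did not pass camera (adjusted p = 0.0998) and passed fry as lower (adjusted p = 9.6e-05).

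From young to mature panicle 2 of the 3 phased-siRNA triggers rose in WT. The list did not pass camera (adjusted p = 0.12, and adjusted p = 0.60 with an estimated correlation). It passed fry as higher (adjusted p = 6.9e-07). So did the machinery families (fry adjusted p = 1.5e-07) and the 25 families together (0.0021), which did not pass camera either. Passing fry but not camera as lower were the phase change and inflorescence (fry adjusted p = 0.000145), monocot-specific (0.0021) and nutrient and stress (0.0030) lists. The 22-nt and 24-nt sequences did likewise (fry adjusted p = 1.7e-06 and 1.8e-05). miR2275 had 0 reads in young panicle and 110 in mature panicle, at least 22.8-fold higher, and miR2118 rose 22.9-fold, from 5.17 ± 1.98 to 120.6 ± 13.5. miR164, miR167 and miR159 rose 4.82-, 4.45- and 4.33-fold, and the call of miR167 ended with 3′ variants added. miR535 fell 10.1-fold, miR1432 5.4-fold, miR408 3.63-fold, miR156 2.93-fold and miR319 2.70-fold, and miR172 did not pass (adjusted p = 0.21). In all 12 families rose and 6 fell. Over all features 7106 rose and 8431 fell, and 7882 features passed with the lines as 1 group and 6270 with the read-length term. Of those that fell, 2604 belonged to the class found almost only in WT young panicle, again as its choice implies. At 24 nt 3698 rose and 4280 fell, and 2201 of these falls belonged to that class.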

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

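The differences between tissues given here were planned, and those between the lines and all tests of explanations in this part were chosen after the results had been seen.

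The change in ago18 against WT differed between tissues, by a test of the difference itself, for 7368 features between young panicle and seedling, 6809 between mature panicle and seedling and 9092 between mature and young panicle. Library making and panicle stage are not separated from genotype in these differences, as given above. Differences between young panicle and seedling passed for miR528 (5.54 on the log2 scale), miR398 (4.23), miR156 (3.17), miR1432 (0.995), miR168 (0.993), miR408 (0.99) and miR159 (0.925). Between mature panicle and seedling they passed for miR535 (5.69), miR528 (4.70), miR398 (4.67), miR156 (4.22), miR1432 (3.83) and miR162 (1.26), and for miR168 (-0.523), miR159 (-1.15) and miR2118 (-2.86). Between mature and young panicle they passed for miR1432 (2.84) and miR156 (1.06), and for miR168 (-1.52), miR393 (-1.55), miR159 (-2.07) and miR2118 (-3.92). The value for miR2275 also passed, but its fitted -7.20 is set against 0 WT young panicle reads, so its size is not measured. The lines differed from each other for 8807 features in seedling, 17841 in young panicle and 9967 in mature panicle. Reads of 25 to 36 nt, outside the main measurement, held the sequence TAACACTGTGACAATACACCG in 310 cases over the 12 ago18 libraries and in 0 over the 6 WT libraries. Reads of 16 to 19 nt, also outside it, made up 37.1% of ago18(2) young panicle replicate 1 (Wilson 95% interval 37.02% to 37.12%), above the WT libraries.

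The families miR398, miR528, miR408, miR827, miR169, miR535, miR156, miR1432 and miR162 were lower in seedlings of both ago18 lines, at least 3.66-fold on the mean of the lines. The scaling was excluded as the whole cause, since with the total alone the median change was -2.329. A sequence bias of the 4 WT libraries trimmed apart cannot be told apart from genotype. Each family had a higher log2 change in young panicle, by a median of 2.517, and miR156 rose there, but reads ending in 7 adapter bases were 30.05 times as frequent in WT seedling as in WT young panicle, so the bias need not be equal. Growth or harvest conditions of the WT seedlings cannot be told apart from genotype either, because 0 ago18 seedling libraries were trimmed like the WT ones and no label gives conditions, and an effect of the knock-down stays open beside both.

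In ago18(1) seedlings, 113 21-nt sequences of WT mature panicle that were nearly absent from WT seedlings were found at a median 0.959 of their mature panicle level. Carry-over from a panicle library, or tissue like the panicles sampled here, would as the sole source bring 24-nt sequences along at the same ratio. These reached the seedlings at no more than 0.1246 of the 21-nt ratio for any panicle group. This argues against either as the source of all the 21-nt sequences, but not of a part. Of 1293 24-nt sequences chosen in the same way, 1091 stood at 1 RPM or more in ago18(1) seedlings and 18 in ago18(2) seedlings. An effect of equal size in both lines is argued against by ago18(2) seedlings, where the median ratio was 0, with 9 of the 113 at 1 RPM or more. The sum over the 113 in WT seedlings, 2.47 RPM, was held low by how they were chosen and is no baseline. Summed over the 113, the level was still 374 RPM in ago18(2) seedlings, against 2918 in ago18(1) seedlings. A shared effect of unequal size is thus not argued against. Panicle tissue of a stage not sampled here cannot be told apart from a change in this line, because both raise miR2118, which was 1.429 log2 units higher than in ago18(2). What stays open is tissue of such a stage in these samples, an effect of that line alone, or a shared effect that is weaker in ago18(2). Carry-over or tissue like the sampled panicles also stays open as a part of the source.

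WT young panicle held 3204 sequences at 5 RPM (reads relative to 20- to 24-nt reads) or more that were under 0.3 RPM in every other group, 3.63% of its 20- to 24-nt reads, against at most 139 in another group. Degraded RNA of another organism is argued against by length, since 84.27% of them were 24 nt long, and another plant in place of rice by the 3 sequences missing of 4962 shared by all other groups. Adapter bases left by trimming are argued against by the ends, since 0.1852% of the 2700 24-nt sequences ended in 5 to 7 bases of the adapter start. A panicle stage held only by the WT young panicle samples cannot be told apart from a genotype effect, as the ago18(1) young panicle profile had r = 0.8917 with WT mature panicle (0.803 for ago18(2)), across sequences, which are not independent replicates. An admixture of another plant at a few percent, and foreign RNA for the part that is not 24 nt long, also stay open.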

How the results depend on the processing

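The 32 results that answer a comparison were recomputed under 443 alternatives, and 391 kept their direction and their side of the threshold, or a count within 1.5 times; the exceptions follow, and unless a reason is given the cause was not tested. The read-length term, the removal of sequences ending in the adapter start, the default quasi-likelihood options, and every alternative for single lines, for lines against each other and for differences between tissues were chosen after seeing the data. With both lines as 1 group, where by construction differences between lines enter the spread, 3927 features passed in seedling, 9342 in young panicle and 222 in mature panicle, with 10, 10 and 2 miRNA families. WT mature against young panicle then gave 7882, and the differences between tissues 3110 (young panicle and seedling), 1465 (mature panicle and seedling) and 2038 (mature and young panicle). A minimum count of 5 admits more features. It gave 17962 calls in seedling and 33728 in young panicle, for ago18(1) 23098, 44852 and 6808 in seedling, young and mature panicle, and for ago18(2) 14594, 36080 and 13892. For WT it gave 63643 between young panicle and seedling and 38308 between mature and young panicle, with 10322 for the difference between mature panicle and seedling and 40963 between the lines in young panicle. A term for the longest read length, which only ago18(1) young panicle with 1 library of each kind can estimate, left 3317 calls in seedling and 7701 in young panicle, 7161 for ago18(1) and 2640 for ago18(2) in seedling, 6289 for ago18(2) in young panicle, 6270 for WT mature against young panicle, and 3460 and 5972 for mature panicle against seedling and against young panicle. DESeq2 gave 3671 in mature panicle, 2253 for ago18(1) and 5968 for ago18(2) there, and 5437 and 6054 between the lines in seedling and mature panicle. Leaving out 1 library at a time assumes that the lone library left in a group varies like the other groups. It gave 6731 to 8498 calls in seedling, 12763 to 15043 in young panicle and 3491 to 5562 in mature panicle, where WT replicate 1 or 2 left 3738 or 3491. It gave 2508 to 2920 for ago18(1) in mature panicle, below the main count without any of the 4 libraries. For ago18(2) in mature panicle it gave 5920 to 6846, and 5797 to 7005 between the lines, both lowest without ago18(2) replicate 2. The replicate block gave 8807, 15081 and 6104 calls in seedling, young and mature panicle. No share of reads in a single tissue can pass 0.05, so only their direction is compared. The 22-nt difference in mature panicle turned to 0.645 points with 20- to 24-nt reads as the base and to 0.412 with distinct sequences, and over the tissues together to 0.117 with distinct sequences. Without single libraries that last difference ranged from -0.783 to -0.572 and passed without ago18(2) young panicle replicate 1 (-0.783). The 24-nt difference in seedling, near 0 at first, was -1.15 with distinct sequences and -1.27 to 1.30 without single libraries, and the 21-nt difference in mature panicle was -0.037 to 0.566. Of 1304 alternatives for 79 named features 1240 kept their side and direction, 59 lost the call, 3 gained it and 2 turned. Of those not kept, 24 came from taking both lines as 1 group. miR167 in young panicle turned to -0.29 with 3′ variants added, and the change of miR2275 from WT seedling to young panicle, -5.54 to 0 without single libraries, vanished without seedling replicate 2 and lost its call without either young panicle library. Multi-mapping reads, phased-siRNA loci and reads of AGO18 need a genome and were not run. Depth limits rare features most, such as miR2275 and miR172 with 0 to 3 reads in some groups.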

Other observations

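The classes and thresholds in this part were chosen after the data had been seen, and are given as values. The lines parted in the panicle sequences of 21 and 24 nt. The 113 21-nt sequences at 10 RPM or more in WT mature panicle and under 0.3 RPM in WT seedling stood at a median 0.0409 of their mature level in WT young panicle, 0.906 in ago18(1) young panicle and 0.195 in ago18(2) young panicle. In mature panicle they stood at 0.932 in ago18(1) and 0.417 in ago18(2). The 1293 24-nt sequences of the same kind stood at 0.541 in WT young panicle, 1.046 in ago18(1) and 0.529 in ago18(2) young panicle, 1.12 in ago18(1) and 0.734 in ago18(2) mature panicle, and 0.119 in ago18(1) seedling. Across sequences, the ago18(1) young panicle profile had r = 0.951 with ago18(1) mature panicle, 0.892 with WT mature panicle and 0.433 with WT young panicle, and that of ago18(2) young panicle 0.803 and 0.489 with the last 2.

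The ago18(2) libraries held more reads outside 20 to 24 nt in all 3 tissues, with 44.2%, 47.7% and 45.1% of the 18- to 30-nt reads in seedling, young and mature panicle, against 34.2% to 37.6% in the other groups. The first base of 24-nt reads was A in 57.9% of reads in WT seedling and in 50.2% and 49.2% in ago18(1) and ago18(2) seedling.

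Reads ending in 5 to 7 bases of the 3′ adapter start made up 0.303% and 0.350% of the WT seedling libraries and 0.0744% and 0.0718% of the WT young panicle libraries, and the other 14 libraries held 0. The longest read was 35 nt in 5 libraries and 36 nt in 13. The 35-nt libraries were those of WT seedling, WT young panicle and ago18(1) young panicle replicate 1.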
